A study of Mus musculus with 8 samples.

How the data were processed

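The deposited values are whole-number read counts per gene, 1 file for each of 8 libraries of laser-captured CD68-positive lesion cells. Per the labels' protocols, the authors pooled captured cells, purified RNA with a PicoPure kit, amplified samples above a stated integrity number with a low-input Nugen Ovation Trio kit and sequenced single ends on an Illumina HiSeq2500. Per the submitters' processing notes, CASAVA, STAR, Picard, HTSeq, DESeq2, bedtools and R 3.3.0 were used with genome build mm10; which tool did what, the annotation and the strand setting are not given in the sources used here. The counts carry no normalization. Low-input amplification without molecular identifiers means that reads are not independent molecules, so depth gives counting precision only.

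Each file held 48397 gene rows and 5 summary rows for reads assigned to no gene, and 20385 genes had no read in any library. The summary rows made up 27.0% to 28.7% of all counted reads and were left out of library sizes and tests. Groups came from the titles, which give the marrow genotype, the sex of the marrow donor and a donor number. Donor numbers did not recur between the groups, so no pairing was used. A cohort number that accompanies the deposited files (1, 2, 1 and 4 libraries in cohorts 1 to 4) served for an alternative only. Replicates are separate donors by their labels.

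Genes were kept with filterByExpr of edgeR 4.0.16 by genotype (minimum count 10), leaving 16350. Counts were scaled by TMM and fitted with edgeR's robust quasi-likelihood model (glmQLFit, glmQLFTest) with genotype and donor sex as terms, or with their interaction. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. CPM values use TMM library sizes. Fixed gene lists (41, of which 38 with at least 5 tested members entered the tests and the rest checked labels or were too small) covered retinoid, lipid and macrophage biology, other cell types and RNA quality. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation, with fry and by exact permutation of mean log2(CPM + 1). Values per library were compared by exact permutation tests, two-sided. Gene positions came from a RefSeq table of the same assembly as mm10, which matched 90.0% of tested genes by symbol. Only 7 of the mitochondrial protein genes entered the tests; several others, such as mt-Co2, are listed at 0 in all libraries.

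Genes named in the text follow a rule fixed before the data were examined: Bco1, Bco2 and Ldlr, the 12 genes with the smallest p in each direction, 2 members of each list (smallest p in lists on biology, highest level in the others) and every called member, Xist and Y-linked genes, 5 autosomal genes in each direction for sex and 5 for the interaction. Rhou and some genes described per library in the closing section, such as Ucp1, Jchain, Actc1, Mb, Myl2 and Myl3, fall outside it. These, and the libraries picked out for other genes there, were chosen after their values were seen.

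Alternatives were other scalings (RLE, totals alone, totals without mitochondrial, ribosomal protein and haemoglobin genes), other filters, DESeq2 1.42.0, limma-voom with quality weights, no robust shrinkage, other terms, cohort 4 alone, female marrow alone, a threshold of 0.10 and leaving out each library. R 4.3.3 was used. The fits were tested on counts simulated from the real means, library sizes and edgeR's dispersion estimates, with 200 genes changed 1.5-, 2- or 4-fold. In the simulation of genotype, 5 of the 83 genes edgeR called and 33 of the 133 DESeq2 called were unchanged ones, and camera called the 1 changed list of 40 genes and none of the others. Genes were drawn independently there, so the unchanged lists had no correlation between genes. The simulation therefore says nothing about camera's preset correlation for lists whose genes vary together.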

Results

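RNA was sequenced from CD68-positive cells, the macrophage-rich fraction of an atherosclerotic lesion, cut by laser from the aortic root of mice lacking both Ldlr and Bco1 that had been irradiated and given marrow from wild-type or Bco1-/- donors. Bco1 encodes the enzyme that splits β-carotene into retinal, so the comparison asks what its presence in marrow-derived cells does to the transcripts of lesion macrophages. There were 4 libraries with wild-type marrow (donors 27, 39, 44 and 47) and 4 with Bco1-/- marrow (donors 38, 42, 46 and 50). Marrow came from female donors in 3 wild-type and 2 Bco1-/- libraries and from male donors in 1 and 2. Each donor number occurs once, and the sex of the recipient of each library is not given in the sources used here. Between 40680257 and 49524801 reads per library were assigned to genes, and 19900 to 22475 genes had at least 1 read. No pair of libraries agreed within sampling noise, the lowest chi-square per gene being 37.4, and log CPM correlated between libraries at r from 0.971 to 0.986 across genes, which are not independent replicates.

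Macrophage transcripts were abundant in both groups. Lyz2, which encodes lysozyme, was read at 17393 ± 3714 CPM with wild-type marrow and 23419 ± 7257 CPM with Bco1-/- marrow (SD, n = 4 each), and the cathepsin gene Ctss at 7592 ± 1054 and 8100 ± 1391 CPM. The listed macrophage identity genes took 4.35% ± 0.487 and 4.91% ± 0.905 of gene reads (exact permutation p = 0.371, two-sided). Transcripts of other vessel wall cells were present too, among them the matrix gene Dcn at 5683 ± 757 and 4656 ± 1475 CPM and the smooth muscle actin gene Acta2 at 1499 ± 333 and 1446 ± 570 CPM.

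The targeted gene was scarcely read in either group. Bco1 (chromosome 8, 117095851 to 117133720, build mm10) had 23 to 59 reads per library, or 0.735 ± 0.436 CPM with wild-type marrow and 0.961 ± 0.206 CPM with Bco1-/- marrow (SD, n = 4 each). The log2 fold change was 0.47 ± 0.55 (SE), with an adjusted p of 0.9997 in edgeR's quasi-likelihood test. The deleted part of the gene is not given in the sources used here and reads were counted over the whole gene, so these counts check nothing about the labels. Bco2, which encodes the related enzyme that cuts carotenoids off-centre, was at 2.48 ± 0.403 and 1.89 ± 0.565 CPM (log2 fold change -0.54 ± 0.34, edgeR adjusted p = 0.9997). Ldlr, the low-density lipoprotein receptor gene missing in the recipients, was at 22.6 ± 6.69 and 24.3 ± 14.4 CPM (log2 fold change 0.08 ± 0.46, edgeR adjusted p = 0.9997).

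In the edgeR fit no single gene passed the threshold for marrow genotype, against 43 with DESeq2 and 2 with limma-voom, and the genes with the smallest p among those higher with Bco1-/- marrow were led by genes of atrial heart muscle. Myl4, an atrial myosin light chain gene, was at 11.6 ± 2.71 CPM with wild-type and 42.6 ± 11.1 CPM with Bco1-/- marrow (SD, n = 4 each), a log2 fold change of 1.81 ± 0.22 (SE) with an edgeR adjusted p of 0.154. Sln, which encodes the calcium pump regulator sarcolipin, was at 5.13 ± 2.34 and 29.4 ± 10.5 CPM (log2 fold change 2.42 ± 0.32), Myl7 at 14.4 ± 7.61 and 69.1 ± 22.9 CPM, and Nppa, the atrial natriuretic peptide gene, at 7.16 ± 3.26 and 51.0 ± 32.5 CPM. In Mybphl the levels were 1.11 ± 0.581 and 9.21 ± 3.04 CPM. The 2 groups did not overlap in any of these 5 genes, and the remaining 7 genes of the highest 12 were Abcc8, Cdk5rap1, Igkv6-23, Igkv4-57, Wdfy1, Rag1 and Trim54.

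**Figure D1:**
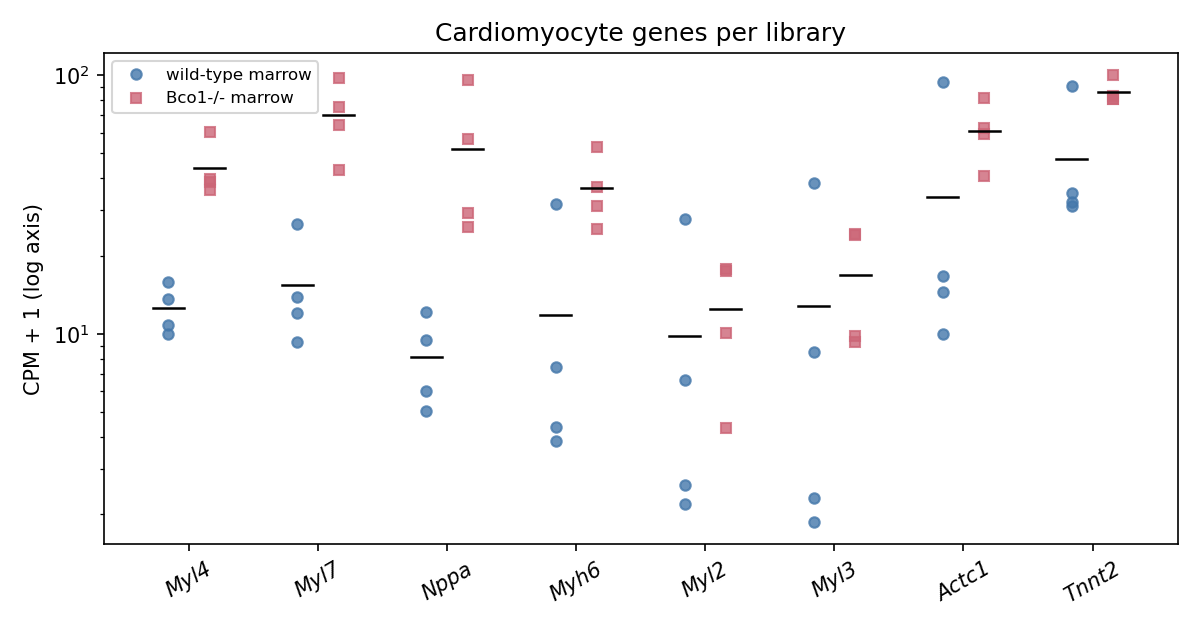
Level of 8 cardiomyocyte genes in each library, as CPM + 1 on a log axis, with circles for wild-type marrow, squares for Bco1-/- marrow and bars at the mean of 4 libraries. In Myl4, Myl7 and Nppa all 4 squares lie above all 4 circles, whereas in Actc1 and Myl2 the wild-type library 27 (93.2 and 26.9 CPM) lies above every square.

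Among the genes lower with Bco1-/- marrow, Pi16, a peptidase inhibitor gene known from fibroblasts, was at 54.9 ± 6.11 CPM with wild-type and 23.8 ± 4.53 CPM with Bco1-/- marrow (log2 fold change -1.19 ± 0.16, edgeR adjusted p = 0.154). Limch1 was at 44.5 ± 7.48 and 26.4 ± 1.19 CPM, Mtus1 at 44.8 ± 6.04 and 26.3 ± 3.99 CPM, and Tmem204 at 63.0 ± 5.11 and 41.3 ± 8.61 CPM. Apold1, a gene of activated endothelium, was at 10.1 ± 4.26 and 2.87 ± 0.657 CPM, and the mesodermal transcription factor gene Meox1 at 18.4 ± 3.85 and 9.71 ± 1.62 CPM. Jag2, Plekha6, Sparcl1, Klhdc4, Pcdhb7 and Sema6d complete the 12.

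Of 16350 genes tested, 0 passed an adjusted p of 0.05 in edgeR, 601 had an unadjusted p under 0.05 where chance gives 817.5, and DESeq2 called 43 (22 higher and 21 lower) and limma-voom 2. Groups that did not overlap were seen in 388 genes, or 2.37%, where chance gives 2.86%. On a single set of counts simulated for this comparison without any change, edgeR made 0 calls and DESeq2 21 among 15861 genes. The simulation used edgeR's own dispersion estimates, so it does not compare both tools on even terms. In 15883 simulated genes edgeR recovered 81.5% of the 65 changed 4-fold, 27.3% of the 66 changed 2-fold and 10.6% of the 66 changed 1.5-fold. With cohort as a term, 5 genes passed (all higher), and Myl4 had a log2 fold change of 2.09 (edgeR adjusted p = 0.0423). Cohort 1 held only wild-type library 27 and cohort 3 only Bco1-/- library 42. That fit therefore compared the genotypes within the other 6 libraries and is not an adjustment of all 8. Within cohort 4 alone, which held 2 libraries of each group, 0 genes passed and the Myl4 value was 2.17 (edgeR adjusted p = 0.107). Over the 21 alternatives run for Myl4 the log2 fold change lay between 1.68 and 2.17 and the adjusted p between 3.3e-11 (DESeq2) and 0.871 (edgeR without Bco1-/- library 38). Leaving out wild-type library 27 or Bco1-/- library 42 gave 5 genes each and leaving out any of the other 6 libraries 0.

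Most of the listed heart muscle genes were higher with Bco1-/- marrow, but as a group they were called only by camera at its preset correlation. Of 18 tested cardiomyocyte genes 17 were higher (median log2 fold change 1.2), with 0 past the threshold over all genes and 3 (Myl4, Myl7 and Nppa) adjusted over the list alone. Tnnt2, the cardiac troponin T gene, was at 46.3 ± 28.9 and 85.2 ± 9.22 CPM and Atp2a2, the calcium pump gene, at 95.2 ± 10.5 and 102 ± 23.8 CPM (SD, n = 4 each). All 18 endothelial genes were lower (median -0.44, 0 adjusted over the list alone), Pecam1 being at 379 ± 57.1 and 274 ± 56.7 CPM and Emcn at 467 ± 68.7 and 441 ± 182 CPM. Of 18 smooth muscle genes 13 were lower (median -0.21, 0 adjusted over the list alone). Camera with its preset correlation called these lists (adjusted p = 4.7e-27, 6e-11 and 0.0101), but with an estimated correlation the adjusted p was 0.287 for cardiomyocyte, 0.799 for endothelial and 0.946 for smooth muscle genes.

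Genes of antigen presentation, the mitochondrial genome, lymphocytes, the immediate early response and the lysosome formed the rest of the groups called by camera. All 14 tested genes of the antigen presentation list, which holds Ctss, Ciita, Cd80, Cd83 and Cd86 beside MHC class II genes, were higher with Bco1-/- marrow (median 0.28, 0 adjusted over the list alone), among them H2-Oa at 4.29 ± 1.22 and 7.44 ± 1.67 CPM. All 7 mitochondrial genes were lower (median -0.32, 6 adjusted over the list alone), mt-Cytb being at 1965 ± 382 and 1660 ± 255 CPM. T and NK cell genes were higher in 18 of 22 (median 0.61), B and plasma cell genes in 10 of 14 (median 0.67), immediate early genes in 17 of 19 (median 0.19) and lysosomal genes in 30 of 33 (median 0.10), with 0 genes adjusted over the list alone in each. Camera's adjusted p was 0.00366, 2.5e-08, 0.000211, 0.00523, 0.00828 and 0.0222 in that order, and with an estimated correlation it was 0.946 for each but the mitochondrial list, where the adjusted p was 0.799. The fry test called 0 of the 38 lists and exact permutation of list means 0, with a smallest unadjusted exact p of 0.0857. After adjustment over 38 lists the permutation test passes only if 22 or more lists reach the smallest p of the design, so its count says little.

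The cardiomyocyte, endothelial and mitochondrial lists were called by camera at the preset correlation without each of the 8 libraries, with medians from 0.85 to 2.24, from -0.66 to -0.30 and from -0.46 to -0.23. With an estimated correlation none of them was called on all 8 libraries. The cardiomyocyte value of 2.24 was that without wild-type library 27 and the endothelial value of -0.66 that without wild-type library 47. Antigen presentation genes were not called without Bco1-/- library 46 (median 0.08, camera adjusted p = 0.244) or 50 (0.13, 0.0746). T and NK cell genes were not called without Bco1-/- library 46 (0.0038, 0.770) or wild-type library 39 (0.40, 0.0671). B and plasma cell genes were not called without Bco1-/- library 38 (0.59, 0.174) or 46 (0.25, 0.0856) or wild-type library 39 (0.17, 0.0671). Immediate early genes were not called without Bco1-/- library 46 (-0.03, 0.770) or wild-type library 27 (0.11, 0.221). Smooth muscle genes were not called without Bco1-/- library 38 (-0.05, 0.811) or 42 (-0.16, 0.138) or wild-type library 27 (-0.12, 0.297), nor lysosomal genes without Bco1-/- library 38 (-0.05, 0.127) or 42 (0.09, 0.238) or wild-type library 39 (0.05, 0.247). Other medians moved by over 1.5 times while the list stayed called: without wild-type library 47 to 0.44 (antigen presentation), 1.35 (T and NK cell), 1.64 (B and plasma cell), 0.17 (lysosome) and -0.33 (smooth muscle), without Bco1-/- library 46 to 0.20 (lysosome) and -0.34 (smooth muscle), and without Bco1-/- library 50 to 1.08 (B and plasma cell) and -0.40 (smooth muscle). Without Bco1-/- library 46, 16 lists were called. With library totals alone as the scaling, which lowered the median of all genes from 0.0048 to -0.04, the lysosome median was 0.04 (24 of 33 higher).

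**Figure D2:**
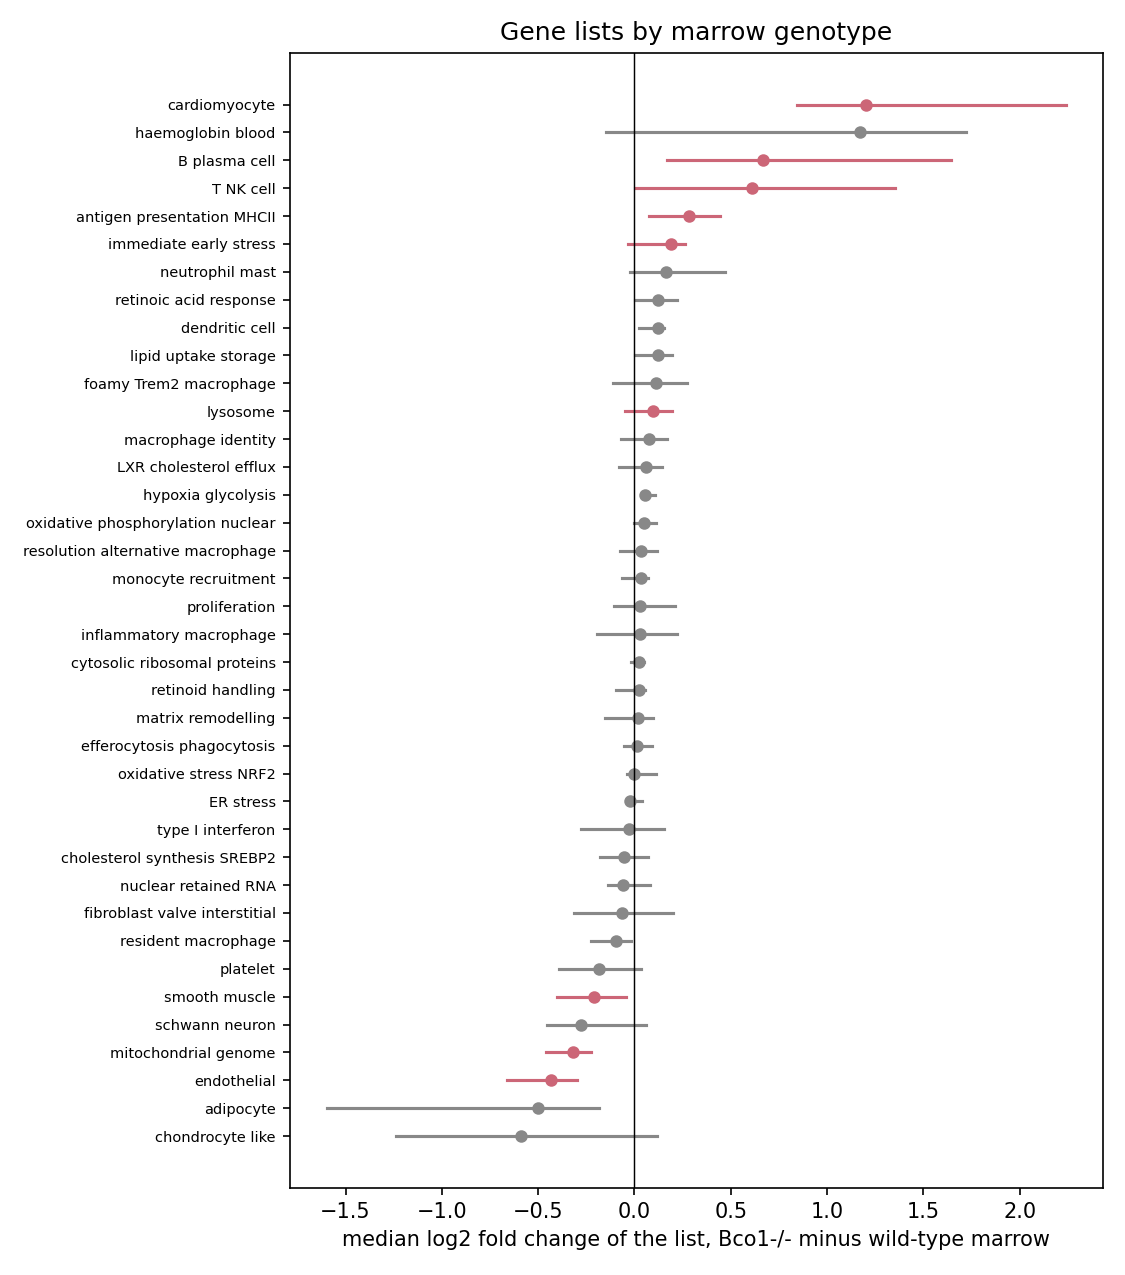
Median log2 fold change of each of 38 gene lists, Bco1-/- minus wild-type marrow, with a line from the lowest to the highest median when 1 library is left out and red for lists called by camera with the preset correlation. Cardiomyocyte genes have the highest median of the called lists at 1.2 and endothelial genes at -0.44, while most macrophage lists lie near 0.

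Lists on retinoids and lipids, the subject of the study, were not called with all 8 libraries. Retinoid handling genes were split, 12 higher and 11 lower (median 0.02, mean -0.06, camera lower with an adjusted p of 0.738), and Aldh1a2, which encodes a retinal dehydrogenase, was at 3.01 ± 0.709 CPM with wild-type and 1.30 ± 0.474 CPM with Bco1-/- marrow (SD, n = 4 each; log2 fold change -1.26 ± 0.39, edgeR adjusted p = 0.9997). Library totals alone as the scaling lowered the median of all genes as well, from 0.0048 to -0.04. With that scaling, the median of the retinoid handling list was -0.02, that of LXR and cholesterol efflux genes 0.0066 (12 of 21 higher), that of inflammatory genes 0.0033 (14 of 27 higher), that of retinoic acid response genes 0.08 and that of cholesterol synthesis genes -0.10. Retinoic acid response genes were higher in 19 of 26 (median 0.12, camera adjusted p = 0.316). Lipid uptake and storage genes were higher in 20 of 24 (median 0.12, camera adjusted p = 0.150). Cholesterol synthesis genes had a median of -0.05 (10 of 22 higher, camera adjusted p = 0.754) and the LXR and cholesterol efflux genes one of 0.06 (16 of 21 higher, camera adjusted p = 0.333). Inflammatory macrophage genes had a median of 0.03 (16 of 27 higher, camera adjusted p = 0.977). Without 1 library the medians ranged from -0.09 to 0.06 for retinoid handling, 0.0015 to 0.22 for retinoic acid response, 0.0049 to 0.20 for lipid uptake, -0.18 to 0.07 for cholesterol synthesis, -0.08 to 0.14 for LXR and cholesterol efflux and -0.19 to 0.22 for inflammatory genes. Lipid uptake and LXR genes were called higher by camera at the preset correlation without Bco1-/- library 46 (medians 0.20 and 0.14), and an estimated correlation was not run with libraries left out. Among inflammatory genes, Cebpb was at 219 ± 25 and 296 ± 45.6 CPM and the chemokine gene Ccl2 at 244 ± 46.1 and 195 ± 38.3 CPM. Timd4, a receptor gene of resident macrophages, was at 0.482 ± 0.211 and 4.33 ± 2.78 CPM (log2 fold change 3.16 ± 0.73, edgeR adjusted p = 0.9997) and was the 1 gene adjusted over the list alone in the resident macrophage and in the phagocytosis list. Its groups overlapped, Bco1-/- library 42 being at 0.415 CPM, within the wild-type range of 0.262 to 0.717 CPM.

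Genes lying near Bco1 were examined because a knockout line can carry a segment of its strain of origin. Klhdc4 (chromosome 8, 121796308 to 121829583) was at 26.0 ± 2.18 CPM with wild-type and 13.4 ± 2.81 CPM with Bco1-/- marrow, and Rhou (123653929 to 123663880) at 17.3 ± 3.53 and 7.97 ± 2.69 CPM (SD, n = 4 each), with edgeR adjusted p of 0.535 and 0.861. Within 10 Mb of Bco1, 2 of 158 tested genes had an unadjusted p under 0.01, against 109 of 14559 elsewhere (odds ratio 1.70, 95% interval 0.201 to 6.39, Fisher's exact p = 0.335, two-sided).

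Mitochondrial transcripts took 0.730% ± 0.103 of gene reads with wild-type and 0.579% ± 0.0619 with Bco1-/- marrow (SD, n = 4 each). The exact permutation p was 0.0571, two-sided, where 0.0286 is the smallest the design allows, and 0.56 after adjustment over the library measures. A single measure at that smallest value could not have passed this adjustment either, so the adjusted value says little. Within cohort 4 the shares were 0.746% and 0.864% against 0.518% and 0.661%. Library totals were 46276134 ± 3200474 and 44196764 ± 2792064 gene reads (exact permutation p = 0.371).

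The sex of the marrow was visible in Y-linked genes. Ddx3y, a Y-linked helicase gene, was at 0.142 CPM in the 5 libraries from female marrow and 24.5 CPM in the 3 from male marrow, a log2 fold change of 7.16 ± 0.41 (SE, edgeR adjusted p = 0.000346), and Eif2s3y was at 0.0621 and 19.5 CPM. Y-linked genes together were at 0.239 ± 0.122 and 51.0 ± 11 CPM (SD, n = 5 and 3). Xist, the transcript that silences an X chromosome in female cells, was at 196 ± 18.5 CPM with female marrow and 90.3 ± 26.5 CPM with male marrow (log2 fold change -1.09 ± 0.19, edgeR adjusted p = 0.321), so it was read in libraries from male marrow as well. Usp9y, Zfy1, Zfy2 and Sry had no read in any library.

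**Figure D3:**
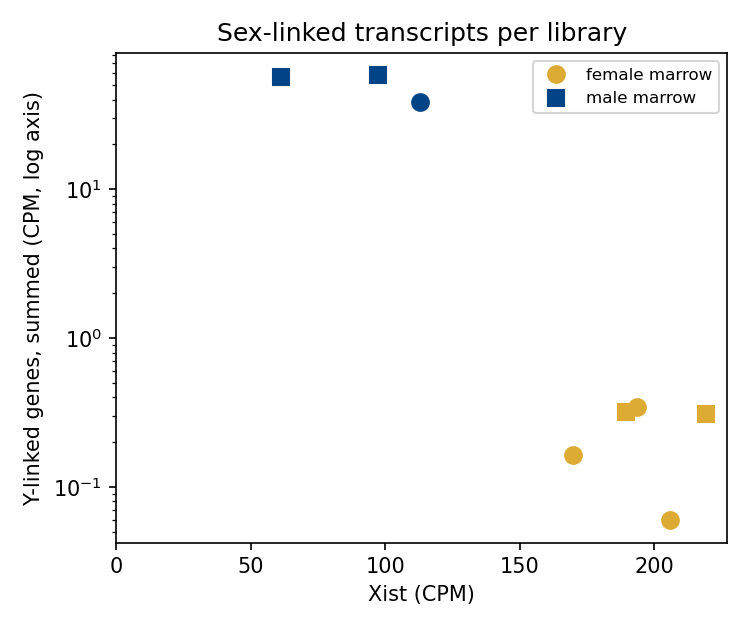
Xist on the horizontal axis (CPM) against the sum of Y-linked genes on the vertical axis (CPM, log axis) in each library, coloured by the sex of the marrow, with circles for wild-type and squares for Bco1-/- marrow. The 3 libraries from male marrow lie at 61.1 to 113 CPM of Xist and the 5 from female marrow at 170 to 219 CPM.

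Igkv8-28, an immunoglobulin light chain segment, was the other gene that passed (log2 fold change 6.39 ± 0.57, edgeR adjusted p = 0.00987, 0.343 and 33.9 CPM). Its reads can be shared with near-identical segments. Igkv10-96, Znhit2, Mrpl15 and Ndufa7 were the autosomal genes next in order among those higher with male marrow, at log2 fold changes of 6.81, 0.55, 0.45 and 0.46, and Sntb2, Mmp14, Pdcd6ip, Zfp871 and Leng8 led those lower, at -0.67, -0.63, -0.67, -0.65 and -1.08. EdgeR called 2 genes, both higher, and 1966 had an unadjusted p under 0.05 where chance gives 817.5. DESeq2 called 151 and limma-voom 3. The filter by genotype removed the Y-linked genes Eif2s3y, Kdm5d and Uty before these tests, and with a filter by sex edgeR called 5 genes. Without wild-type library 47, the lone male one of its genotype, edgeR called 0 genes (1650 at an unadjusted p under 0.05), and without Bco1-/- library 42 or 50 it called 1. It called 6 without Bco1-/- library 38, 5 without wild-type library 27, 39 or 44 and 4 without Bco1-/- library 46.

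Measures of read assignment were compared between the sexes too, and none passed after adjustment over the 14 measures. The smallest exact permutation p that 5 against 3 allows is 0.0179. Even the summed Y-linked genes had an adjusted exact permutation p of 0.0625, so failing this adjustment says little. Reads aligned to several places made up 15.1% ± 0.396 of all counted reads with female and 16.2% ± 0.168 with male marrow (SD, n = 5 and 3; exact permutation p = 0.0179, two-sided, adjusted 0.0625). Reads that matched no counted gene feature made up 5.88% ± 0.694 and 4.59% ± 0.243 (exact permutation p = 0.0357, adjusted 0.1), and 21798 ± 591 and 20788 ± 840 genes were detected (exact permutation p = 0.107, adjusted 0.25). The annotation and strand setting are not given, so some of these unmatched reads may lie within genes. Within cohort 4 the first share was 15.32% and 14.45% in the female libraries and 16.35% and 16.04% in the male ones, the second 6.13% and 6.30% against 4.84% and 4.58%, and the genes detected 21959 and 22475 against 21569 and 20894.

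Ribosomal protein genes were higher with male marrow in 72 of 77 (median 0.26, 14 adjusted over the list alone) and nuclear genes of oxidative phosphorylation in 41 of 46 (median 0.25, 14 adjusted over the list alone). Immediate early genes were lower in 18 of 19 (median -0.36, 0 adjusted over the list alone) and nuclear-retained RNAs in 7 of 10 (median -0.56, 5 adjusted over the list alone), the list including Xist. Without Xist the median of its other 9 RNAs was -0.55 (6 lower). Malat1 was at 1058 CPM with female and 720 CPM with male marrow and Neat1 at 662 and 434 CPM. Adipocyte genes were higher in 11 of 11 (median 2.64) and B and plasma cell genes in 13 of 14 (median 1.93). The adipocyte median was 0.94 without Bco1-/- library 42, and the mean log2(CPM + 1) of the list in male library 50 (2.04) lay within the range of the female libraries (1.58 to 2.76). The immediate early median was -0.17 without Bco1-/- library 46. Camera called 14 of 38 lists, 12 higher and 2 lower, with adjusted p of 4.4e-15, 4.8e-13, 1.9e-05, 0.000532, 4.4e-06 and 2.8e-09 for those named, in order. With an estimated correlation 0 were called, the adjusted p being 0.648 for immediate early genes and 0.559 for the other 5. The other 8 called lists, all higher, were mitochondrial, haemoglobin, proliferation, macrophage identity, interferon, foamy macrophage, resident macrophage and T and NK cell genes, with estimated-correlation adjusted p of 0.559 to 0.939. Without wild-type library 47 the B and plasma cell list and 6 of these 8 were not called (camera adjusted p from 0.0618 to 0.995; B and plasma cell median 0.68), and T and NK cell genes were called lower (median -0.61). Proliferation genes lost their call without Bco1-/- library 38 or 50 (camera adjusted p = 0.222 and 0.0931), and so did interferon genes (0.0501 and 0.848). Without Bco1-/- library 46 the foamy, identity and resident macrophage lists were not called (0.891, 0.302 and 0.186), nor was the foamy list without library 42 (0.0836). T and NK cell genes were not called without wild-type library 27, 39 or 44 (0.0505, 0.138 and 0.0594), nor resident macrophage genes without library 27 (0.0855). The fry test for one direction and exact permutation called 0 as well, the smallest unadjusted exact p being 0.0179, which is the smallest that 5 against 3 allows. At least 14 of the 38 lists would have to reach it to pass after adjustment, so this count of 0 says little. The fry test for change in either direction called 5 lists: resident macrophage (adjusted p = 0.00123), nuclear-retained (0.0208), ribosomal protein and oxidative phosphorylation (0.0347 each) and phagocytosis (0.0482). With library totals alone as the scaling, which lowered the median of all genes as well (from -0.03 to -0.13), the ribosomal protein median was 0.17 (71 of 77 higher), that of oxidative phosphorylation 0.15 (38 of 46 higher), that of T and NK cell genes 0.20 (14 of 22 higher), that of proliferation genes 0.06 (18 of 30 higher), that of foamy macrophage genes 0.07 and that of interferon genes 0.19. Among the other 8 lists, medians also moved by over 1.5 times while the list stayed called: without Bco1-/- library 38 to 0.37 (foamy macrophage) and 3.10 (haemoglobin), without library 42 to 0.61 (interferon) and 0.72 (T and NK cell), without library 46 to 0.50 (interferon), 0.28 (proliferation) and 0.82 (T and NK cell), without library 50 to 0.52 (T and NK cell), without wild-type library 44 to 0.15 (resident macrophage) and without library 47 to 0.34 (proliferation).

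In the edgeR fit the effect of marrow genotype was not found to differ by sex in any gene, against 31 genes with DESeq2. The smallest p belonged to Gzma, Rnase1, Pkhd1l1, Lpar4 and Gpm6a, Gzma having a log2 difference of -3.82 between the genotype effects in male and female marrow (edgeR adjusted p = 0.918). EdgeR called 0 of 16350 genes, with 727 at an unadjusted p under 0.05, and DESeq2 called 31. A single library held wild-type male marrow, so its spread was assumed to be that of the other groups.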

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

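The tests of explanations in this part, the counts over other splits included, were chosen only after the results were seen. In 252 groups of values examined for a library far from the others, 18 stood out where chance gives about 12.6. Of these 6 concerned Bco1-/- library 46: macrophage identity genes took 3.56% of its reads (5.26% to 5.54% in the other 3 libraries of its group), Lyz2 was at 12711 CPM (25355 to 28539), Pros1 at 71.4 CPM (59.4 to 60.7), Lcn2 at 221 CPM (148 to 157), the cartilage matrix gene Comp at 664 CPM (98.3 to 133) and Jag2 at 0.040 CPM (0 in the others). The Jag2 value lies near the floor and stands out only because the others had no read. In Bco1-/- library 38, Wdfy1 was at 49.7 CPM (67.9 to 71.8) and Car9 at 0.381 CPM (3.17 to 4.07). In Bco1-/- library 42, Igkv6-23 was at 0.389 CPM (8.37 to 11). In Bco1-/- library 50, Ighm was at 277 CPM (33.4 to 41.1) and Tnnt2 at 98.9 CPM (79.6 to 82.2). In wild-type library 27, Bco1 was at 1.39 CPM (0.464 to 0.557), Rag1 at 0.188 CPM (0.020 to 0.040) and Tnnt2 at 89.6 CPM (30.3 to 34.2). The Rag1 values lie near the floor as well. In wild-type library 44, Comp was at 142 CPM (322 to 367). In wild-type library 47, reads aligned to several places made up 16.3% (15.2% to 15.3%), Gzma was at 6.57 CPM (0.705 to 0.896) and Pkhd1l1 at 5.53 CPM (14.8 to 16.8).

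Other groupings of the same libraries were compared with the real ones. For genotype, 0 genes were called in edgeR (43 by DESeq2), which all 35 splits of the libraries into 4 and 4 reach by construction, so that count decides nothing; the highest other split gave 8. At an unadjusted p under 0.05 in edgeR there were 601 genes, which 22 of the 35 splits reached, the highest other with 1536. Lists called for genotype numbered 9, which 32 of the 35 splits reached and the highest other split exceeded with 22. For sex, 2 genes were called, 5 of 56 splits gave as many and the highest other gave 8. The filter by genotype was used in all of these fits, so this count leaves out the Y-linked genes Eif2s3y, Kdm5d and Uty. At an unadjusted p under 0.05 the real split by sex had 1966 genes, which 2 of the 56 splits reached, the highest other with 1998. Of lists, 14 were called for sex, 35 of the 56 splits gave as many and the highest other gave 22. The splits did not take cohort into account, and cohort was not a term in their fits. Each count of splits includes the real one, and splits close to the real one share part of its difference. By these splits chance is not excluded for the number of genes called for sex, the number at that p for genotype or either count of lists. This concerns the counts and not Ddx3y itself, which is Y-linked and was at 14.5 CPM or more in each male library and at most 0.222 CPM in each female one. The genes at that p for sex were reached by under 5% of the splits, but this was 1 of several counts, looked at after the others, and another split, of wild-type libraries 39 and 44 with Bco1-/- library 46 against the rest, had more. That other split put all male libraries on the same side, and sex was not a term in its fit. It therefore held part of the sex difference and is no independent measure of chance.

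Cardiomyocyte genes were higher with Bco1-/- marrow by camera at the preset correlation, but not with an estimated one (adjusted p = 0.287). A lower share of macrophages alone, with the other cells in unchanged proportions, would raise the genes of every other cell type. That is argued against by the endothelial list, with a median log2 fold change of -0.44, negative without each library (-0.66 to -0.30). A lower share together with more heart muscle is not tested by this list. Macrophage identity genes took 4.35% of gene reads with wild-type and 4.91% with Bco1-/- marrow (exact permutation p = 0.371). Heart muscle caught with the aortic root lesion is a candidate source, which stays open. After removing genotype and sex, the 18 genes correlated at a mean r of 0.432 across libraries. This was above all 10000 random lists matched on level (highest 0.318) but under the 0.5 set for this explanation. Random lists are a weak comparison, because genes of other cell types varied together too. Camera's estimated correlation was 0.397 for cardiomyocyte, 0.532 for endothelial and 0.610 for T and NK cell genes, though 0.135 for dendritic cell genes. With genotype removed, the correlation cannot show what caused the genotype difference. The genotype of the marrow stays open too, with an exact permutation p of 0.0857 for the list mean. Haemoglobin genes were higher with Bco1-/- marrow as well (6 of 6, median 1.17), though camera at the preset correlation did not call them (adjusted p = 0.0609).

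Xist was read in libraries from male marrow at 46.2% of its mean level with female marrow. Reads exchanged between libraries would carry Y-linked transcripts into libraries from female marrow as readily, yet these stood at 0.468% of the male level. A wrong sex label is not supported by the Y-linked genes, whose lowest male level was 112 times the highest female level. Female cells of the recipient, which irradiation and transplantation do not replace outside the marrow lineage, may carry the Xist reads, but recipient sex per library is not given in the sources used here and this cannot be told apart from other origins.

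Ribosomal protein and oxidative phosphorylation genes were higher, and immediate early genes and nuclear-retained RNAs lower, with male marrow. A single library as the whole cause is argued against, since the 4 lists kept their direction and were called by camera at the preset correlation without each of the 8 libraries (largest adjusted p = 0.0120). With an estimated correlation none was called with all libraries (adjusted p = 0.648 for immediate early genes and 0.559 for the others), and the immediate early median shrank from -0.36 to -0.17 without Bco1-/- library 46. A trend with transcript length and GC content remains possible for part of the pattern, since with both as an offset the 4 lists were still called by camera at the preset correlation but medians shrank from 0.26 to 0.13, 0.25 to 0.08, -0.36 to -0.23 and -0.56 to -0.31, and oxidative phosphorylation kept 31.8% of its median. The sex of the marrow cannot be told apart from other differences of the 3 male libraries, since both divide the libraries alike. The adjusted exact permutation p of the ribosomal protein list, 0.226, decides nothing, because its unadjusted p of 0.0179 was already the smallest the design allows.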

How the results depend on the processing

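Tests chosen only after the results were seen are those without Bco1-/- library 42 and wild-type library 47 together, the filter by sex, the length and GC offset, and exact permutation of list means. The cause of the changes below was not tested.

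Genes changed with genotype (0) numbered 3 without a filter, 43 with DESeq2, 2 with limma-voom, 5 with cohort as a term, 1 in female marrow alone, 3 without libraries 42 and 47, and 0 to 5 without 1 library (5 without wild-type 27 or Bco1-/- 42). Lists called with genotype (9) numbered 0 with an estimated correlation, 0 with fry for one direction, 0 by permutation, 14 without the sex term and 8 to 16 without 1 library (16 without Bco1-/- 46).

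Genes changed with sex (2) numbered 4 without a filter, 1 with the strict filter, 151 with DESeq2, 1 without the genotype term, 4 in cohort 4 alone, 5 with the filter by sex and 0 to 6 without 1 library. Lists called with sex (14) numbered 0 with an estimated correlation, 0 with fry for one direction (5 for either direction) and 0 by permutation, and 11 to 15 without 1 library. The interaction (0) gave 31 genes with DESeq2 and 1 without a filter, and has no value without wild-type 47, which leaves no wild-type male library. Without 1 library the genotype median ranged from -0.11 (without Bco1-/- 38, called lower) to 0.27 (without Bco1-/- 46, called higher) for foamy macrophage genes, which were also called higher without wild-type 47 or Bco1-/- 50, and from -0.048 (without 38, not called) to 0.20 (without 46) for lysosomal genes. The sex median of T and NK cell genes ranged from -0.61 (without wild-type 47, called lower) to 0.82 (without Bco1-/- 46).

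The odds ratio near Bco1 was 1.57 to 2.76 with other windows and an unadjusted p of 0.05. The genotype differences in library total and mitochondrial share kept their direction without each library and stayed above the threshold. Among values not called in either fit, 99 of 2341 gene values and 137 of 817 list values changed sign. Simulated recovery of 2-fold changes for sex was 35.4%, so differences of that size or under are often missed at this number of libraries.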

Other observations

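The values per library in this part were picked after they were seen, and no further test was run on them. Several of the genes, such as Myl4, Cfd, Hbb-bs and Igkc, had entered the fits above. Transcripts of fat, blood and antibody-producing cells differed widely between libraries. Cfd, the adipsin gene, was at 115 CPM in Bco1-/- library 42 and 38.6 CPM in wild-type library 47 and at 0.547 to 23.9 CPM in the other 6, and the brown fat gene Ucp1 was at 18.1 and 4.48 CPM in these 2 libraries and 0.352 to 2.62 CPM in the others. Haemoglobin gene Hbb-bs ranged from 17.7 CPM in wild-type library 27 to 626 CPM in Bco1-/- library 42. Igkc, the kappa light chain gene of antibodies, was at 3.31 CPM in wild-type library 39 and 299 to 3766 CPM in the others, and Jchain was at 0.378 CPM in the same library.

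Heart muscle genes were arranged differently across libraries. In wild-type library 27, Actc1 (93.2 CPM), Mb (92.8 CPM), Myl2 (26.9 CPM) and Myl3 (37.4 CPM) were as high as or higher than in most Bco1-/- libraries, while Myl4 (14.9 CPM), Myl7 (12.9 CPM) and Nppa (8.46 CPM) lay below every Bco1-/- library. In wild-type libraries 44 and 47 Myl2 was at 1.19 and 1.59 CPM and Myl3 at 0.867 and 1.32 CPM.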
